A study of Mus musculus with 8 samples.

How the data were processed

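Single-cell RNA was measured with the droplet-based 10x platform in stomach gland cells of mice of 1 genotype, Atp4bCre; Rosa26NICD; Arid1a flox/flox, at 23 weeks of age. In these animals Cre is expressed from the promoter of Atp4b, a subunit gene of the gastric proton pump of parietal cells. Cre switches on the intracellular domain of Notch, a constitutively active form of the receptor, from the Rosa26 locus and removes the floxed part of Arid1a, which encodes a DNA-binding subunit of the BAF chromatin remodelling complex. Per the labels' protocols, glands were digested with collagenase and dispase, and cells with high EPCAM staining and low uptake of the dead-cell dye Sytox Blue were sorted before library preparation. The sort takes epithelial cells, so the shares of cells below describe the sorted fraction only. The labels list 8 samples of this genotype and do not say whether they came from separate animals.

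The authors deposited 1 table of whole-number counts for the whole series, with gene symbols in rows and cell barcodes in columns. The submitters' processing notes name Cell Ranger, Seurat 2.3.0 and the mouse build mm10, without the role or the order of each. The version of Cell Ranger, the gene annotation and any filter on cells or genes before deposit are not given in the sources used here. The counts are not normalised: column totals differ from cell to cell. They were read as unique molecular identifiers (UMIs), which is what Cell Ranger tables hold, since the labels do not state it. The barcodes are 16 bases long and carry no sample number, so the 1460 barcodes were treated as 1 sample and no cell was assigned to any of the 8 samples. The number of value columns left unused was 0.

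The table as used here covers part of the genome. It holds 780 gene symbols, of which 712 match the GENCODE vM21 annotation of GRCm38, the assembly that mm10 names. All 712 lie on chromosome 1, between positions 3102016 and 90014666. The other 68 symbols were kept under the names in the file. The last row, Asb18, holds 928 of 1460 values, all of them 0, and was left out, which leaves 779 genes. Genes elsewhere in the genome were not analysed here. Cell totals are therefore totals over this part of chromosome 1 and not library depth, and every level is relative to the UMIs of the table. A gene's level moves when the few most abundant genes move, because 40.2% of the UMIs belong to 3 genes.

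Barcodes with fewer than 100 UMIs were left out, which kept 1388 of 1460 barcodes and 439743 of 444786 UMIs. Counts were turned into Pearson residuals of a model with the cell total and the gene's share (overdispersion parameter 100, residuals limited to 10 in size). Genes seen in at least 20 cells entered a principal component analysis, except the members of the fixed gene lists, so that the levels of listed genes are not set by the clustering. The first 8 components of 264 genes gave a graph of 15 nearest neighbours weighted by shared neighbours. The graph was partitioned with the Leiden algorithm (leidenalg 0.10.2, igraph 0.11.9) at resolution 0.5, and clusters were numbered by size. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and scikit-learn 1.9.0 was used. The filter on cells, the residuals, the number of components and the resolution were set after seeing the data. Of 7 recipes tried, this one was kept because in log-normalised values the leading component followed the cell total, in real and in noise-only tables alike, and because its small clusters recurred over random seeds. Scrublet in scanpy 1.11.5 called 0 of 1388 cells doublets, so doublets were not removed. Its power on counts from part of 1 chromosome was not tested, so 0 calls do not exclude doublets.

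Before the data were examined, 32 gene lists with 273 different genes were fixed, among them markers of stomach, intestinal, immune and stromal cell types. A row in the table was found for 10 of these genes, in 7 lists. No cell type had more than 1 measured marker, and 3 are needed for a name, so clusters carry numbers. Arid1a and the fixed lists of BAF subunits, Notch targets and p53 targets have no row in the table and were not analysed here. The tests planned across the 8 samples, with edgeR and DESeq2, need a map from cells to samples and were not run.

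The level of a gene in a set of cells is given in CPM: its summed UMIs over all UMIs of the table in those cells, times 1000000, with an exact Poisson 95% interval. Ratios of levels carry an exact interval from the conditional binomial distribution, and shares an exact Clopper-Pearson interval. These intervals cover counting error only: cells are not replicates, all values come from 1 pooled sample, and no p-value is given. They are too narrow for a gene whose UMIs sit in a few cells. A limit for a count of 0 uses 3 counts over the group. Log2 fold changes use a pseudocount of 1 CPM. The rule for named genes was fixed in advance: all measured members of the fixed lists, and for each pair among the 3 most abundant named cell classes the 10 genes with the highest and the 10 with the lowest fold among genes with at least 50 UMIs over the pair. No cluster could be named, so the 3 largest clusters took the place of these classes. Ribosomal protein genes and cell type markers were left out of that rule. A mean level of 50 CPM was also asked for. The same rule applied to each cluster against all other cells gave the genes that describe the cluster. Those genes were used to make the clusters, so their folds describe the partition and are not independent results. Some named genes are not reported here. The median of a list was set against 10000 random lists of the same size, drawn from the 20 genes nearest in expression to each member. Unlike the list members, the genes drawn include ones used to make the clusters.

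The ratio and the clustering were tested on simulated cells drawn from the real profile and cell totals. Over 240 genes in 2 known groups of cells, 96% of the intervals held the true ratio for the 50 genes set to a log2 change of 1 and 98.3% for the 58 genes set to -2. For the latter the median true log2 ratio was -2.67, because raised genes take a share of the total, and the median estimate -2.69. In 10 tables with a group of 20% and a group of 5% of cells, each with 20 genes raised 4 times, the clustering over 264 genes found 3 clusters in each table, with an adjusted Rand index of 0.892 to 1. The raise of 4 times is above the median ratio of the leading genes in real clusters 1, 2, 3, 4 and 6 (2.04 to 2.71), though not in cluster 5 (4.95). Simulated cells of a group differ only by counting, so these tests do not cover further spread between real cells. Tables drawn from 1 profile with no groups were also partitioned, into 2 to 5 clusters in 20 tables, so a cluster number alone shows no structure.

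Alternatives planned beforehand and run were no filter on cells, Leiden resolutions of 0.25 and 1, a pseudocount of 5 CPM, median-of-ratios scaling and thinning of each cell to 100 UMIs. A further 5 were chosen after seeing the data: log-normalised values for clustering, the deepest 5% of cells left out, another random seed, 5 principal components, and clusters made without any of the 75 named genes. Lists of T lymphocyte genes, endocrine granule genes and ribosomal protein genes were written after the gene symbols had been seen. Counts of Rpl7, Rpl31, Rpl37a, Ptma, Hspe1 and Eef1b2 are uncertain, since these genes have processed pseudogenes and how shared reads were counted is not given in the sources used here. Hspd1 and Hspe1 overlap in the annotation by 111 bases on opposite strands.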

Results

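The series measured single-cell RNA in sorted epithelial cells of stomach glands from Atp4bCre; Rosa26NICD; Arid1a flox/flox mice at 23 weeks. Its title places it in a study of how the dosage of Arid1a acts in gastric tumours. The labels give 8 samples and 1 genotype, so no genotype was compared. The comparisons below are between groups of cells within the pooled table, which counts as 1 sample with no replicates. The table held 444786 UMIs in 1460 barcodes, with a median of 279 UMIs and 71 genes per barcode. Totals ranged from 2 to 1082 UMIs, and from 189 to 394 between the 25th and the 75th percentile. These totals cover the first 90 Mb of chromosome 1 and are not library depth.

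The most abundant transcripts came from 3 ribosomal protein genes and Ptma. Rpl37a, a ribosomal protein gene (chromosome 1, 72711290 to 72713813), took 19.4% of all UMIs, followed by Rpl7 (11.5%), Ptma, which encodes prothymosin alpha (9.35%), and Rpl31 (9.31%). Cox5b, a subunit of cytochrome c oxidase, took 4.75%, and the translation elongation factor gene Eef1b2 4.52%. Hspe1, which encodes a mitochondrial chaperonin, took 2.68%. The 10 most abundant genes held 66.3% of the UMIs. Of 779 genes, 418 had a UMI in any barcode and 241 had at least 50.

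**Figure D1:**
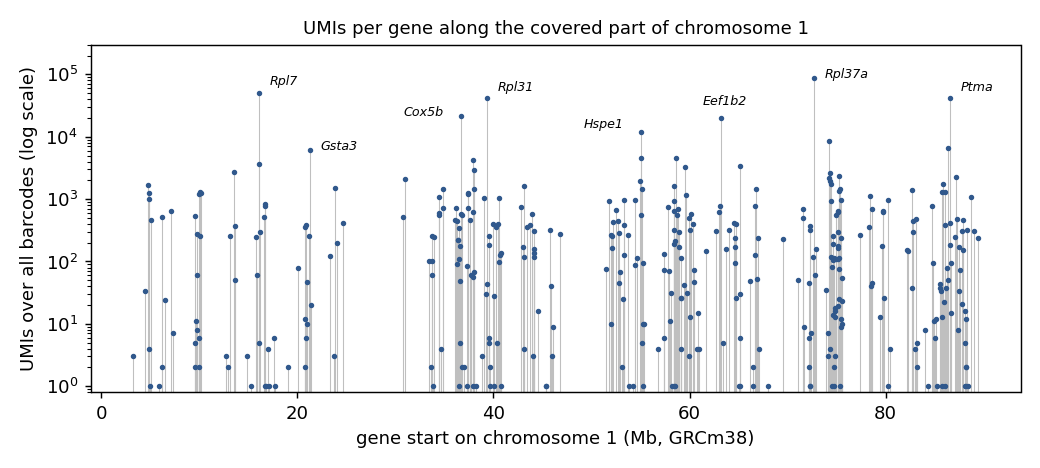
Summed UMIs of each gene with a UMI and an annotated position (points, log scale) against the start of the gene on chromosome 1 of GRCm38, in Mb. Rpl37a stands highest with 86209 UMIs, and Rpl7, Ptma and Rpl31 hold between 41399 and 51222.

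Among the genes of the fixed lists, the actin-bundling protein gene Vil1 (chromosome 1, 74409376 to 74435559) stood for the intestinal list, with 1747 UMIs. Of the 15 listed Myc targets 4 were measured: the nucleolar protein genes Ncl (6481 UMIs) and Nop58 (1159), and the mitochondrial chaperonin genes Hspd1 (4603) and Hspe1 (11927). The replication helicase gene Mcm3 (chromosome 1, 20802968 to 20820312) had 354 UMIs, and Casp8, which encodes an initiator caspase, 703. The fibroblast gene Col3a1 and the smooth muscle gene Des had 1 UMI each.

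After barcodes with fewer than 100 UMIs were left out, 1388 cells (median 286 UMIs) fell into 6 clusters. Cluster 1 held 616 cells, 44.4% (41.7 to 47.0), and cluster 2 held 328 cells, 23.6% (21.4 to 26.0), with intervals for counting error in parentheses. Cluster 3 held 181 cells, 13.0% (11.3 to 14.9), and cluster 4 held 177 cells, 12.8% (11.0 to 14.6). The small clusters 5 and 6 held 56 cells, 4.03% (3.06 to 5.21) and 30 cells, 2.16% (1.46 to 3.07). Cells of cluster 3 were deeper than the others, with a median of 487 UMIs against 270 in cluster 1 and 266.5 in cluster 2. The summed share of Rpl7, Rpl31 and Rpl37a was 36.6% in cluster 3 and 34.8% in cluster 4, below the 42.4% of cluster 1 and the 43.6% of cluster 2. The border between clusters 1 and 2 moved with the settings: at resolution 0.25 a single cluster with 70.6% of cells took the place of cluster 1, and no match of cluster 2 was left.

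Cluster 3 was described by a mixed set of genes, among them Prim2 and Mcm3 of DNA replication and Sgol2 and Hjurp of the centromere. Its leading genes against all other cells were Sgol2, a protector of centromeric cohesion (11.0-fold higher, 5.85 to 22.0, 39 UMIs), 2810408I11Rik (5.31-fold, 3.48 to 8.15), the BRCA1 partner gene Bard1 (5.21-fold, 2.89 to 9.52) and the primase subunit gene Prim2 (3.73-fold, 2.47 to 5.62). Ccnyl1, Hjurp, which encodes a chaperone of the centromeric histone, 1700019D03Rik, Mars2 and Slc23a3 followed, between 1.87-fold and 2.34-fold. Mcm3 was the remaining 1 of its 10 leading genes and, unlike the others, had no part in the clustering. When all 10 were left out of it, the best matching cluster still had all 10 at a higher level than the other cells, with a median ratio of 2.28 against 2.42 before.

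Genes that had no part in the clustering were also higher in cluster 3. Mcm3 reached 1533 CPM (1286 to 1813) there against 609.7 (531 to 697) in all other cells, a ratio of 2.51 (2.01 to 3.13). All 4 measured Myc targets were higher in cluster 3: Hspd1 1.75-fold (1.64 to 1.86), Nop58 1.56-fold (1.36 to 1.77), Hspe1 1.38-fold (1.32 to 1.43) and Ncl 1.30-fold (1.23 to 1.38). Their median log2 fold of 0.55 lay above 99.9% of random lists. Random lists hold genes drawn one by one, whereas Hspd1 varied together with Hspe1 (residual correlation 0.368) and with Ncl (0.259), so this percentile and those below can overstate how far the list stands out. Vil1 was at 0.802 times (0.704 to 0.912) the level of the other cells. Casp8 did not differ detectably, at 0.896 times (0.734 to 1.09) that level. By depth, the Mcm3 ratio was 2.28 (1.70 to 3.07) among cells of 400 or more UMIs and 1.28 (0.640 to 2.32) among cells of 200 to 400 UMIs, where only 12 Mcm3 UMIs came from cluster 3. Among cells of 100 to 200 UMIs it was 9.03 (2.67 to 24.4), from 5 Mcm3 UMIs in 7 cells of cluster 3.

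**Figure D2:**
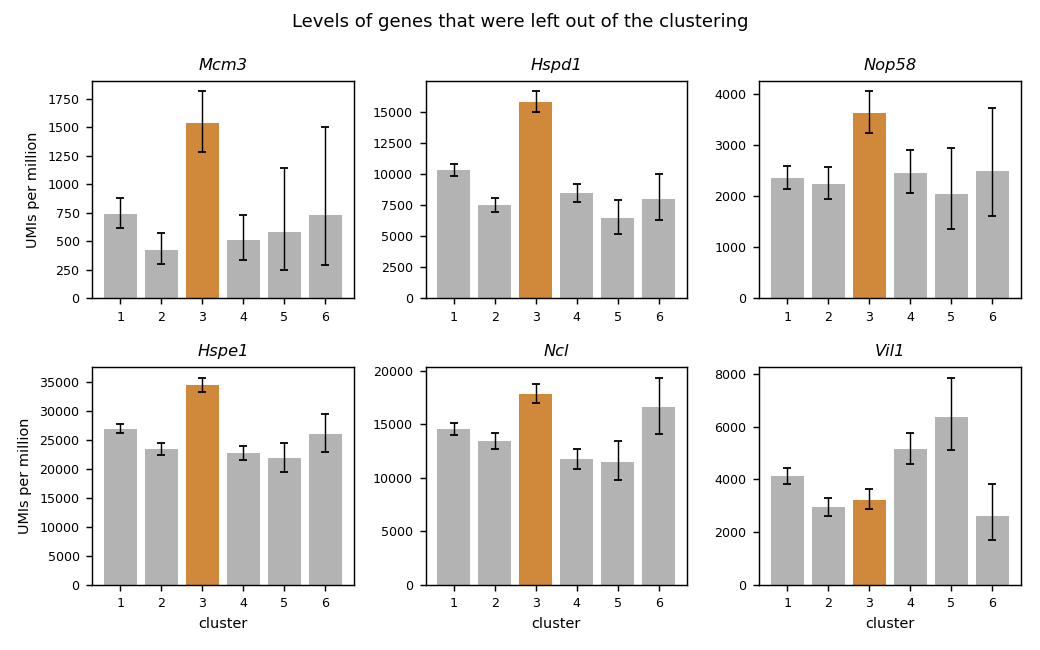
Levels of 6 genes that had no part in the clustering, in CPM of the table, in each of the 6 clusters. Bars are summed levels and whiskers exact Poisson 95% intervals, which cover counting error only. Cluster 3 (orange) has the highest bar for Mcm3 (1533) and for the 4 Myc targets, with an interval that overlaps that of cluster 6 for Mcm3, Nop58 and Ncl. Vil1 has its highest bar in cluster 5 (6383, 5120 to 7864), with an interval that overlaps that of cluster 4 (5150, 4578 to 5773).

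Set against cluster 1 alone, cluster 3 had higher levels of 2810408I11Rik, with a ratio of 4.35 (2.66 to 7.28), Prim2 (3.03, 1.90 to 4.88), Ccnyl1 (2.23, 1.52 to 3.26) and Ptma (2.10, 2.05 to 2.15). Mcm3 was 2.07 times as high (1.61 to 2.65). Hjurp, Il18rap, Mars2, the tubulin gene Tuba4a and Alpi completed the 10 highest, between 1.69 and 1.98 times. The lowest ratios belonged to the secretory granule gene Resp18 (0.0314, 0.000782 to 0.181) and the insulin-like growth factor binding protein genes Igfbp5 (0.0618, 0.0125 to 0.186) and Igfbp2 (0.0824, 0.00970 to 0.314). The fibronectin gene Fn1 was at 0.313 (0.230 to 0.419) and Itm2c at 0.368 (0.301 to 0.446), followed by the insulin receptor substrate gene Irs1, Dst, Rhbdd1, Dis3l2 and Pecr between 0.386 and 0.466. In cluster 1, 60 of the 63 Resp18 UMIs came from 3 cells, and without them its level in cluster 1 was 0.411 times that of the cells outside cluster 1. Igfbp2 had 25 of 48 UMIs in 3 cells. The Myc targets had a median log2 fold of 0.49, above 98.9% of random lists, and all 4 were higher in cluster 3. With cells thinned to 100 UMIs the log2 folds of Il18rap (-0.11), Dst (0.41) and Dis3l2 (0.03) turned, each within counting error. Alpi turned to -0.45 without the deepest cells and to -1.56 with 5 components. At resolution 1 the clusters held too few UMIs to place Resp18 and Igfbp2, with 1 UMI each in cluster 3 and 0 in cluster 1, and the same held for Resp18 with 5 components. Igfbp5 stayed lower in cluster 3 in every alternative that was compared. The log2 folds of Fn1 (-1.68) and Itm2c (-1.44) shrank to -0.90 and -0.38 at resolution 1. With cells thinned to 100 UMIs they grew to -2.22 and -1.81.

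Set against cluster 2, the highest ratios of cluster 3 were those of 2810408I11Rik, Prim2 and Mcm3. The ratio of cluster 3 to cluster 2 was 8.42 (3.82 to 21.9) for 2810408I11Rik, 4.38 (2.29 to 9.04) for Prim2, 3.64 (2.54 to 5.32) for Mcm3 and 3.40 (2.31 to 5.12) for the Wnt receptor gene Fzd5. Ccnyl1, Spats2l, Cnnm4, Abcb6, Sgpp2 and Hspd1 followed, between 2.10 and 3.32 times. On the other side, cluster 3 had no UMI of Ptprn, which encodes a membrane protein of secretory granules, against 87 in cluster 2, at least 27.1-fold lower. This limit depends on the partition: cluster 3 stayed at 0, but cluster 2 held only 7 UMIs with another seed (at least 2.36-fold), 6 without the deepest cells (at least 1.42-fold) and 3 with 5 components, too few for a limit. The small GTPase gene Arl4c was at 0.0755 (0.0557 to 0.100) of its level in cluster 2, Tm4sf20 at 0.129 (0.0829 to 0.192), the interleukin receptor gene Il1r1 at 0.266 (0.177 to 0.390) and the retinol dehydrogenase gene Rdh10 at 0.269 (0.237 to 0.303). Itm2c, the transcription factor genes Ikzf2 and Klf7, and Dst lay between 0.262 and 0.388, and Dst turned when cells were thinned to 100 UMIs (log2 fold 0.33). The Arl4c fold shrank from log2 -3.73 to between -2.62 and -2.20 with no filter on cells, without the deepest cells, with another seed or with 5 components. The Tm4sf20 difference depended on the partition too: its log2 fold of -2.96 shrank to -0.30 with no filter on cells, -0.0997 at resolution 1, -0.17 with another seed and -0.32 with 5 components. The Myc targets had a median log2 fold of 0.63, above 99.5% of random lists.

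Clusters 2 and 1 differed most in Arl4c and Ptprn, higher in cluster 2, and in Resp18 and Igfbp2, higher in cluster 1. The Resp18 difference rests on the same 3 cells of cluster 1, and Igfbp2 turned with 5 components (12 UMIs in cluster 2 against 2) and did not differ detectably without the named genes (13 against 11). Arl4c was 9.28 (7.75 to 11.2) times as high in cluster 2, Ptprn 8.92 (5.32 to 15.7), Tm4sf20 3.99 (3.15 to 5.09), Il1r1 2.87 (2.18 to 3.80) and Rdh10 2.07 (1.92 to 2.25). The intestinal alkaline phosphatase gene Alpi, the sterol hydroxylase gene Cyp27a1, Arid5a, Klf7 and Bag2 made up the rest of the 10 highest, between 1.96 and 2.59 times, with 76 of the 87 Alpi UMIs of cluster 2 in 3 cells. Cluster 2 was lower for Resp18 (0.146, 0.0460 to 0.360), Igfbp2 (0.154, 0.0403 to 0.420), Fn1 (0.198, 0.137 to 0.280) and Spats2l (0.298, 0.227 to 0.386), and for Fzd5, Igfbp5, Slc23a3, Sgpp2, Bcs1l and Farsb between 0.394 and 0.541. Igfbp5 turned beyond counting error with 5 components (38 UMIs in cluster 2 against 20), and within it without the named genes (69 against 60). Mcm3 was at 0.568 (0.388 to 0.815) of its level in cluster 1. Of the Myc targets Hspd1, Hspe1 and Ncl were lower in cluster 2 and Nop58 did not differ detectably (0.952, 0.803 to 1.13), with a median log2 fold of -0.16 that lay above 25.4% of random lists, within their range. Ncl changed sign in 5 alternatives and Hspe1 in 1, so of the 4 only Hspd1 kept its direction throughout. Of the 3 pairs compared, this one had the most folds that changed sign: with another random seed Ptprn, Tm4sf20 and Alpi turned to log2 folds of -0.50, -0.78 and -0.84, and in clusters made without any named gene Mcm3 turned to a ratio of 1.44. There the 10 leading genes of cluster 1 against all other cells had a median ratio of 1.36 (2.37 before), with 7 higher. Those of cluster 2 had 1.02 (2.04 before), with 5 higher. With only its own leading genes left out, each cluster kept 9 of 10 higher (medians 1.64 and 1.69). The log2 fold of Arl4c went from 3.21 to 1.87 with no filter on cells, 1.73 without the deepest cells and 1.63 with another seed. That of Ptprn, at 3.14, fell to 0.20 with no filter and to 0.0493 without the deepest cells. With no filter, the log2 fold of Il1r1 also went from 1.52 to 1.10 and that of Rdh10 from 1.05 to 0.49.

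Cluster 4 was described by the glutathione transferase gene Gsta3, at 43948 CPM (42245 to 45702) against 9144 (8844 to 9452) in the other cells, and by Xkr9, B3gnt7, Ikzf2, Cyp27a1, Il1r1 and the sodium/proton exchanger gene Slc9a4, between 2.16-fold and 4.47-fold. Of the genes without a part in the clustering, Casp8 (1.49-fold, 1.22 to 1.81) and Vil1 (1.41-fold, 1.24 to 1.59) were higher in cluster 4. Of the Myc targets Hspd1, Hspe1 and Ncl were lower there and Nop58 did not differ detectably (0.938 times (0.781 to 1.12)). Their median log2 fold was -0.31, below all 10000 random lists. The random lists themselves had a median of 0.19 in cluster 4. They could draw Gsta3, which describes the cluster and is near Ncl in abundance (6008 against 6401 UMIs). This percentile can therefore overstate how low the list stands. Mcm3 was at 0.606 times (0.399 to 0.887) the level of the other cells.

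Cluster 5 was described by Inpp5d, which encodes an inositol phosphatase best known from blood cells, with 47 of its UMIs in this cluster and 4 in all other cells. The tyrosine phosphatase gene Ptpn18 reached 22269 CPM (19847 to 24905) against 1500 (1386 to 1621). The kinase gene Sgk3 (16.8-fold, 9.06 to 30.1), Ogfrl1 (6.49-fold, 3.85 to 10.5) and Fam117b (5.87-fold, 4.52 to 7.53) followed. Vil1, which had no part in the clustering, was 1.69-fold (1.35 to 2.10) as high as in the other cells, and Hspd1 was at 0.613 times (0.491 to 0.756). Cluster 6 was led by the chemokine gene Ccl20, at 28836 CPM (25540 to 32440) against 472 (409 to 542), with at least 1 Ccl20 UMI in all 30 cells. Of its other 9 leading genes, 7 had most of their UMIs in 3 cells. When the leading genes of clusters 4, 5 or 6 were left out of the clustering, the best matching cluster shared few cells with them (Jaccard index 0.168, 0.0684 and 0.0271).

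Levels of chosen genes were also compared without clusters, between barcodes with and without a UMI of Inpp5d or Sgol2. A UMI of Inpp5d was found in 42 of all 1460 barcodes, which had a median of 138 UMIs against 281 in the rest. In these barcodes Ptpn18 was 17.1 (14.8 to 19.6) times as high as in the rest, Sgk3 13.2 (6.55 to 24.8), Fam117b 6.67 (5.01 to 8.76) and Ogfrl1 6.07 (3.21 to 10.6). Klf7 and Stk17b lay between 3.21 and 3.30 times, and Vil1 at 1.93 (1.49 to 2.46). Gsta3 and Rdh10 were lower, at 0.502 (0.386 to 0.644) and 0.350 (0.230 to 0.510). Around Sgol2, with a UMI in 43 barcodes (median 460 UMIs against 275), Bard1 was 4.63 (2.07 to 9.39) times as high, Hjurp 3.41 (2.45 to 4.65), Prim2 3.05 (1.60 to 5.40) and Mcm3 2.76 (1.97 to 3.79), while Hspd1, Ptma and Ncl lay between 1.45 and 1.63. The genes of this comparison were chosen after their values in the clusters had been seen. No other genes were ranked, so it could not have given others. Of the 42 barcodes with Inpp5d, 24 were cells of cluster 5, so it is not independent of that cluster.

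**Figure D3:**
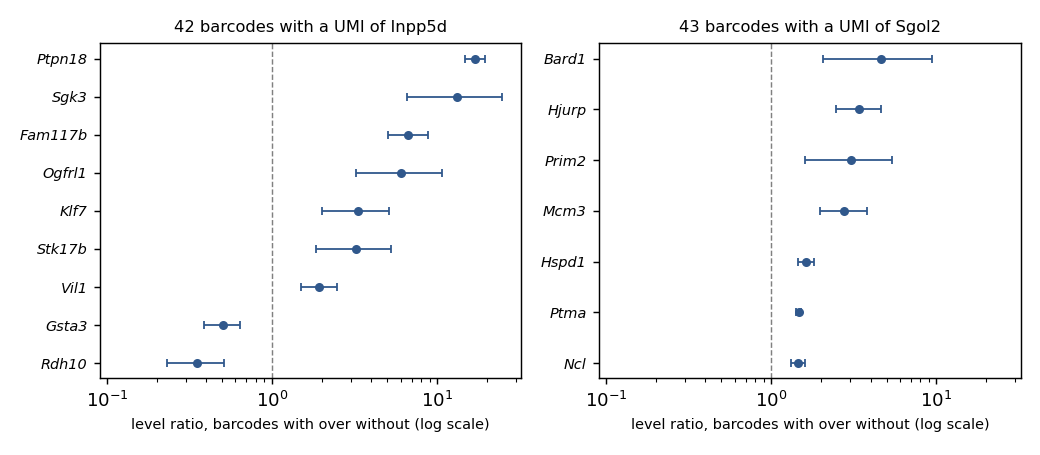
Ratio of gene levels (log scale) between barcodes with and without a UMI of Inpp5d (left, 42 barcodes) or Sgol2 (right, 43 barcodes), with exact 95% intervals for counting error as whiskers and a dashed line at 1. Ptpn18 stands farthest right with 17.1, and Rdh10 and Gsta3 lie left of the line.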

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

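The ratio without Ctla4 was chosen only after the result with it had been seen; the other tests here were chosen after the cluster had been found and before their own values were seen. The barcodes left out for having fewer than 100 UMIs were rich in Inpp5d and Ptpn18. Over these 72 barcodes, Inpp5d reached 4561 CPM (2891 to 6843), 39.3 times its level in the kept cells, from 23 UMIs in 14 barcodes. Ptpn18 reached 26968 (22626 to 31900), 12.5 times its level in the kept cells, from 136 UMIs in 30 barcodes. Both stood out because they lie above the 595 CPM that a count of 0 would allow in these barcodes. Some barcodes with these transcripts thus held few UMIs in the covered part of chromosome 1, and the filter on cell totals removed them.

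The technical explanations weighed were a chance excess, a spread over shallow cells and cells of another type. In the first, the excess belongs to the very UMIs on which the cells were clustered. In UMIs kept out of the clustering, Inpp5d and Ptpn18 together were 18.4 times as high as in the other cells in whichever cluster of each split led in them (median of 10 splits, 3.58 to 23.9), which argues against it. These clusters held 22 to 247 cells and overlapped cluster 5 only in part (Jaccard index 0.179 to 0.603), so the value does not speak for the outline of cluster 5. It is a ratio of summed levels and rests mostly on Ptpn18, with 307 UMIs in cluster 5 against 47 of Inpp5d. It therefore does not show that the 2 genes share cells. Among the 338 cells of 100 to 200 UMIs, the share with an Inpp5d UMI was 0.515 of what an even spread gives (2.96% against 5.74%). The 20 Inpp5d UMIs there thus sat in few of these cells. Barcodes under 100 UMIs, which were rich in Inpp5d, had no part in this comparison, so it does not speak to them. The cluster's outline does rest on its leading genes: with only these 10 left out of the clustering, the nearest cluster shared few cells with it (Jaccard index 0.0684). Without the 75 named genes of all clusters and pairs, no cluster matched it. The nearest one held 437 cells (Jaccard index 0.0625, under the 0.3 needed for a match). Its summed level of Inpp5d and Ptpn18 was 1.61 times that of the other cells (1.42 to 1.83).

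T lymphocytes, which the EPCAM sort would remove, may contribute and cannot be told apart at these counts. The summed level of 6 T lymphocyte genes (Zap70, Cd28, Ctla4, Icos, Stat4 and Il18rap) was 3.46 times that of the other cells (1.79 to 6.16, 13 UMIs). Of these UMIs 7 were Ctla4 in 3 cells, and without Ctla4 the ratio was 1.69 (0.605 to 3.79). Il18rap, the most abundant of them, had 3 UMIs in the cluster and 95 outside it, and the listed Stk17b and Ankrd44 were left out of the sum. The epithelial gene Vil1 was higher in the cluster, not lower. No other cell type was weighed, so an epithelial type stays open. Of the genes of hormone-secreting cells, Cryba2 had 8 of its 15 UMIs in the cluster, Fev 2 of 16 and Resp18 4 of 74, while Scg2 and Ptprn had 0. Whether the cluster holds endocrine cells was not tested. Whether the cluster holds tuft cells was not tested, because 0 of the 6 genes on the fixed tuft list were measured. With 1 genotype in the series, no biological explanation was tested.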

How the results depend on the processing

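Log-normalised values, the deepest 5% of cells left out, another seed, 5 components and clusters made without any named gene were chosen after seeing the data, and the other alternatives beforehand. The Mcm3 excess in cluster 3 stayed between 2.18 and 2.56 times in the 7 alternatives that kept a match of cluster 3; clusters made without any named gene kept none. Of 648 recomputed folds of named genes, 478 moved by less than the counting interval, 134 moved by more and 36 changed sign. With 6 clusters reported, a resolution of 1 gave 10 and clusters made without any named gene 3. Agreement of the partitions (adjusted Rand index) ran from 0.0997 without the named genes to 0.735 with another seed. The share of cluster 5 fell to 2.23% at resolution 0.25; that of cluster 3 went to 35.7% with log-normalised values and to 10.2% without the deepest cells, which cluster 3 holds in excess. Clusters were also lost: 5 components left no match of clusters 5 and 6, log-normalised values none of clusters 2, 4 and 6, resolution 0.25 none of cluster 2, and clusters made without any named gene none of clusters 3 to 6. For the others the cause was not tested.

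The Myc target median kept its sign in every alternative in which both clusters had a match. For cluster 3 against 1 (0.49) it was 0.62 with median-of-ratios scaling, 0.56 at resolution 0.25, 0.36 at resolution 1, 0.61 with log-normalised values, 0.40 without the deepest cells and 0.40 with 5 components. For cluster 3 against 2 (0.63) it was 0.88 at resolution 1, 0.73 with another seed and 0.73 with 5 components. For cluster 2 against 1 (-0.16) it was -0.0398 with median-of-ratios scaling, -0.49 at resolution 1, -0.23 with another seed, -0.39 with 5 components and -0.000139 without the named genes. Median-of-ratios scaling takes off the median log2 fold over genes, -0.14 for cluster 3 against 1 and -0.12 for 2 against 1, and so raised the folds. Where a group held 0 UMIs the size of a log2 fold is set by the pseudocount, and 1 UMI against 0 shows no direction. Folds that changed sign, cluster 3 against 1, as log2: thinned to 100 UMIs, Il18rap -0.11, Dst 0.41 and Dis3l2 0.0298. At resolution 1, Resp18 3.66 (1 against 0 UMIs) and Igfbp2 3.66 (1 against 0 UMIs). With log-normalised values, Dst 0.0528. Without the deepest cells, Alpi -0.45. With 5 components, Alpi -1.56 and Resp18 3.66 (1 against 0 UMIs). Against cluster 2, thinning turned Dst 0.33.

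For cluster 2 against 1, folds turned as follows: with median-of-ratios scaling, Nop58 0.0479 and Ncl 0.00147. Thinned to 100 UMIs, Nop58 0.0131. With no filter on cells, Tm4sf20 -0.52, Alpi -2.07 and Ncl 0.00367. At resolution 1, Tm4sf20 -0.25, Alpi -9.12 (0 against 41 UMIs, at least 5.91-fold lower) and Igfbp2 5.01 (1 against 0 UMIs). Without the deepest cells, Alpi -0.95 and Ncl 0.00654. With another seed, Ptprn -0.50, Tm4sf20 -0.78 and Alpi -0.84. With 5 components, Ptprn -0.21, Tm4sf20 -1.03, Alpi -10.59 (0 against 116 UMIs, at least 33.7-fold lower), Igfbp2 2.74, Igfbp5 1.12 and Ncl 0.0279. Without any named gene in the clustering, Alpi -1.58, Klf7 -0.0507, Igfbp2 0.23, Igfbp5 0.20, Hspe1 0.0354 and Ncl 0.20, and the Mcm3 ratio was 1.44. The cause was not tested. Most of these folds turned in settings that clustered the cells again, and the Myc targets lie near 0 in this pair.

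The real table varied more than counting noise gives: the first 5 components held 9.62% of the variance, 2.55 times the highest of 20 tables simulated from 1 profile, a test chosen after such a comparison had been seen. In UMIs kept out of the clustering, 78.6% to 86.7% of leading genes were still higher in their cluster over 10 splits, with a median log2 fold of 0.67 against 1.19 in the UMIs used. Not run, for want of a map from cells to samples or of a row for the gene, were edgeR and DESeq2 tests, the low count filter, samples left out in turn, the sample block, camera, the correlation across samples, the agreement between samples and the levels of Arid1a and Notch targets. No paired analysis was possible because no cell carries a sample number. Depth limits the rest: at a median of 286 UMIs per cell, a gene of 50 UMIs in the table is seen in few cells, and its interval spans a factor of several.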

Other observations

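The test of Mcm3 within bins of 50 UMIs was chosen only after the other Mcm3 values had been seen, and the ranking of genes by variance and the genes set beside Alpi and Ccl20 after values of theirs. Several transcripts sat in very few cells. Ranked by variance over the Poisson value among genes with at least 50 UMIs in the kept cells, Resp18, a gene of neuroendocrine secretory granules, came first, with 95.9% of its 74 UMIs in 10 cells. The myosin light chain gene Myl1 (92.5% of 53 UMIs in 10 cells) and Alpi (60.7% of 247) followed, and a single cell held 50 Alpi UMIs. Alpi belongs to enterocytes of the intestine in textbooks, and cells with an Alpi UMI were also higher in Vil1 (1.35 times, 1.13 to 1.60), Gsta3 (1.58, 1.45 to 1.72) and Tm4sf20 (2.58, 1.95 to 3.36), but lower in Ccl20 (0.378, 0.194 to 0.666). These cells had a median of 443 UMIs against 275 in the rest. Gsta3, with 6008 UMIs, was found in 72.6% of cells where an even spread gives 95.7%.

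Genes of hormone-secreting cells met in the same cells more often than an independent spread gives, but most cells with Ptprn held none of the others. UMIs of at least 2 of Fev, Cryba2, Scg2, Ptprn and Resp18 were found in 10 cells, 7.83 times the mean of 1000 independent placements (1.28 cells, at most 6). All 4 cells with the serotonergic transcription factor gene Fev also had Resp18, and 9 cells had both Ptprn and Resp18, where 0.456 would be met by chance. Ptprn was found in 40 cells. Of its 113 UMIs 87 were in cluster 2, where Fev, Cryba2 and Scg2 had 0. Of the 74 Resp18 UMIs 63 were in cluster 1, with 14 of the 16 Fev UMIs, 7 of the 15 Cryba2 UMIs and all 13 Scg2 UMIs. Cluster 5 held the other 8 Cryba2 UMIs, 2 of Fev and 4 of Resp18, and 0 of Scg2 and Ptprn. A hypothesis is that a few endocrine cells are in the sort; the fixed enteroendocrine markers have no row here, so they may equally be cells of another kind that share these genes.

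Mcm3 was higher in cluster 3, whose cells are also the deepest, and depth and doublets were weighed. Among cells of 400 or more UMIs, compared within bins of 50 UMIs, the Mcm3 ratio was 2.12 (1.54 to 2.90), which argues against depth as its whole cause there. Among cells of 200 to 400 UMIs the ratio was 1.28 (0.640 to 2.32), and depth cannot be told apart because cluster 3 has 12 Mcm3 UMIs in 48 cells there; below 200 UMIs it was 9.03 (2.67 to 24.4), from 7 cells of cluster 3. Without the deepest 5% of cells, where doublets would gather, the ratio stayed at 2.35 (1.79 to 3.07), although Scrublet called none, so doublets of ordinary depth stay open. No biological explanation was tested.

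Ccl20 was weighed against free RNA, which gives every droplet a like low level. A Ccl20 UMI was found in 9.79% of barcodes, where an even spread of its 480 UMIs gives 27.1%, a ratio of 0.362 that argues against free RNA as the main source. The barcodes with a Ccl20 UMI had a median of 298 UMIs against 278, and in them Tm4sf20 was 1.94 times and Rdh10 1.27 (1.15 to 1.40) times as high, while Il1r1, Gsta3, Sgpp2 and Vil1 showed no rise, at 0.869 to 0.981 times. In cluster 6, 29 of 33 Tm4sf20 UMIs sat in 3 cells. The 10 cells with the most held 41.2% of the Ccl20 UMIs. No biological explanation was tested.

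Because the table covers a stretch of neighbouring genes, it allows a test of whether neighbours vary together. The median residual correlation across cells of 154 adjacent gene pairs that do not overlap was 0.0110, at percentile 92.5 of 1000 random gene orders, which decides neither way. The highest correlation of all 13203 pairs belonged to an overlapping pair, Hspd1 and Hspe1 (0.368), which share a bidirectional promoter and encode partner chaperonins; with overlapping annotations on opposite strands, and strand handling not given in the sources used here, shared reads could add to it. These correlations are across cells of 1 sample, which are not replicates.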
